A study of Mus musculus with 6 samples.

How the data were processed

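RNA of 6 libraries from the brains of 8-month-old APP/PS1 mice was analysed. The labels give the cells as adult astrocytes, and per the labels' protocols RNA was extracted with Trizol, depleted of ribosomal RNA, fragmented and copied into cDNA with dUTP in the second strand, and sequenced as DNA nanoballs. 3 libraries came from mice given saline and 3 from mice given AVE0991 at 10 mg per kg, in both cases by intraperitoneal injection once a day for 30 days. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these libraries.

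The deposited expression table held estimated counts for 36210 gene rows and whole counts for 11824 circular RNA rows, with 1 column per library and no pooling. Per the submitters' processing notes reads were aligned with HISAT to mm9. The versions, the counting program, its use of strand and the annotation are not given in the sources used here. Of the gene rows, 28008 carried Entrez identifiers and 8202 carried identifiers of the sequencing provider without a gene name. Of the deposited estimated counts of gene rows, 81.6% were whole numbers as written. The same table held FPKM values from the authors for each library. They were used only to compare counts with FPKM, and the unit was worked out from the values. A second table held the authors' deposited comparison, with a log2 fold change, a p-value and a q-value per row; per the file headers the p- and q-values came from DESeq2, and the model was not given in the sources used here. The sign of the deposited log2 fold change was AVE0991 over vehicle. 25 gene symbols that had been turned into dates took the symbol of their Entrez identifier in the GRCm38 RefSeq table, which matched 27229 of the 28008 identifiers. Because the reference was GRCm38 and the labels name mm9, it served only for names, biotypes and transcript GC content and length. GC content and length were those of each gene's longest GENCODE M21 transcript. No coordinates are given.

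The estimated counts of gene rows were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM normalization and the robust quasi-likelihood F test of AVE0991 against vehicle without covariates. Benjamini-Hochberg adjustment covered all 20363 genes tested, and a gene was called at an adjusted p under 0.05. The standard error is the log2 fold change divided by the square root of F. CPM values use TMM library sizes and are given as mean ± SD of 3 libraries. Circular RNA rows were fitted apart from gene rows, a choice made after the data were examined. The median of the prior degrees of freedom was 2.93 and the common biological coefficient of variation 24.7% for genes and 38.2% for circular RNAs. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Of 27 lists, 26 had at least 4 measured members. The list of mitochondrially encoded genes had 0 measured members and was not analysed here. The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. Further lists of regional genes, clock genes and glucocorticoid targets, the GC and length corrections and the fits without several libraries were added afterwards.

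The rule for named genes took the genes of the series title with Mas1, Gfap and inflammasome genes (Il1b, Mir223 and its host gene are not analysed here), the 10 genes with the largest change in each direction among those called, with a mean of at least 1 CPM and no overlap between groups, and up to 5 non-coding genes per direction. Places left empty were filled by the smallest p among genes that did not pass, and up to 4 members per list were taken by smallest p. Predicted, pseudogene and unnamed loci were skipped except among non-coding genes. In the higher direction 6 genes passed under this rule, so 4 places were filled by genes that did not pass. Shares called among long non-coding and protein-coding genes were compared with Fisher's exact test, which counts genes as independent.

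Totals ran from 44583274 to 50066615 counts per library for gene rows and from 1424780 to 1581448 for circular RNA rows. The 8202 unnamed rows held 7.45% to 10.5% of the gene counts. All pairs of libraries differed by more than sampling noise, with a chi-square of at least 16.5 per gene over genes with 20 or more counts in the pair, so all 6 counted as separate. The test was run on simulated counts for the 20363 genes with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. It recovered 56% and 91% of them, and 17 of its 164 calls were false. For the 9626 circular RNAs it recovered 12% and 67%, and 1 of 80 calls was false. In 26 simulated lists of 20 genes the 1 list shifted by a log2 of 1 was called, and 0 of the 25 others. The simulated genes varied independently, and the shift was larger than any called list's median, at most 0.54. In the data the estimated correlation within called lists ran from 0.021 to 0.555. This run therefore does not measure false calls among correlated members. With a simulated GC trend and no changed gene, 109 genes were called without and 2 with the GC correction. That correction fits, per library, a loess curve with span 0.5 of the log2 deviation on transcript GC content. 82.8% of the tested genes had a GC value, and the others received no correction.

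The alternatives were DESeq2 size factors, upper-quartile factors, no filter beyond 1 count, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, leaving out each library, other thresholds, other list tests and list members held by 1 list. The pseudocounts planned for normalized values did not apply to counts.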

Results

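The series profiled long non-coding and other RNA in astrocytes from APP/PS1 mice, a line carrying mutant human amyloid precursor protein and presenilin genes that forms amyloid plaques. It compared mice given AVE0991, a synthetic agonist of the angiotensin-(1-7) receptor encoded by Mas1, with mice given saline. There were 3 libraries per group, with 44583274 to 50066615 counts on gene rows. Although the labels name astrocytes, transcripts of other brain cells were abundant in every library. The median level of the neuron list was 350 CPM in vehicle and 389 CPM in AVE0991 libraries, against 193 and 266 CPM for the astrocyte identity list and 165 and 140 CPM for the mature oligodendrocyte list. Each of these values is a median over list members of their group means.

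The first question, taken from the series title, concerned Snhg14, a long non-coding transcript of the imprinted Ube3a locus, and Nlrp3, the sensor of the NLRP3 inflammasome. Snhg14 fell from 16.9 ± 3.79 CPM in vehicle to 2.18 ± 0.133 CPM in AVE0991 libraries (SD, n = 3 each). This was a 7.73-fold decrease, with a log2 fold change of -2.95 (SE 0.19, edgeR adjusted p = 0.0141). The lowest vehicle library stood at 14.6 CPM and the highest AVE0991 library at 2.31 CPM. Nlrp3 was measured at 2.05 ± 0.863 CPM in vehicle and 1.92 ± 0.449 CPM in AVE0991 libraries (log2 fold change -0.09, SE 0.36, adjusted p = 0.902), a difference within the spread between replicates. Its direction changed with single libraries: it was 0.29 without vehicle replicate 1 and 0.07 without AVE0991 replicate 3. Mas1, the receptor gene of the compound, stood at 7.71 ± 3.86 and 4.64 ± 3.31 CPM (adjusted p = 0.58). The AVE0991 mean was lowered by replicate 2, at 0.849 CPM. Without single libraries the log2 fold change of Mas1, -0.73 in the main fit, ranged from -1.16 to -0.23. Gfap, the intermediate filament of astrocytes, stood at 422 ± 70.1 and 550 ± 36 CPM (log2 fold change 0.38, SE 0.15, adjusted p = 0.184). The inflammasome genes Casp1 (0.21, SE 0.41), Pycard (-0.23, SE 0.27) and Il18 (-0.18, SE 0.15) did not pass either. Adjusted over the list alone, Snhg14 was the 1 study gene of 7 that passed, and the others had an adjusted p of 0.125 or more. Snhg14 is on this list because the series title names it, so its place there may rest on these same libraries. Ube3a, a ubiquitin ligase gene transcribed on the opposite strand of Snhg14, fell 1.86-fold, from 110 ± 11 to 58.9 ± 2.92 CPM (log2 fold change -0.90, adjusted p = 0.0374). With any library except AVE0991 replicate 1 left out, the log2 fold change of Snhg14 was -3.04 to -2.75 and its edgeR adjusted p 0.0577 to 0.163. After a correction for GC content Snhg14 stood at -1.96 (SE 0.21, adjusted p = 0.155) and Ube3a at -0.27, and neither passed. Whether the counting used strand is not given in the sources used here, so reads of Snhg14 and Ube3a cannot be told apart where they overlap.

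**Figure D1:**
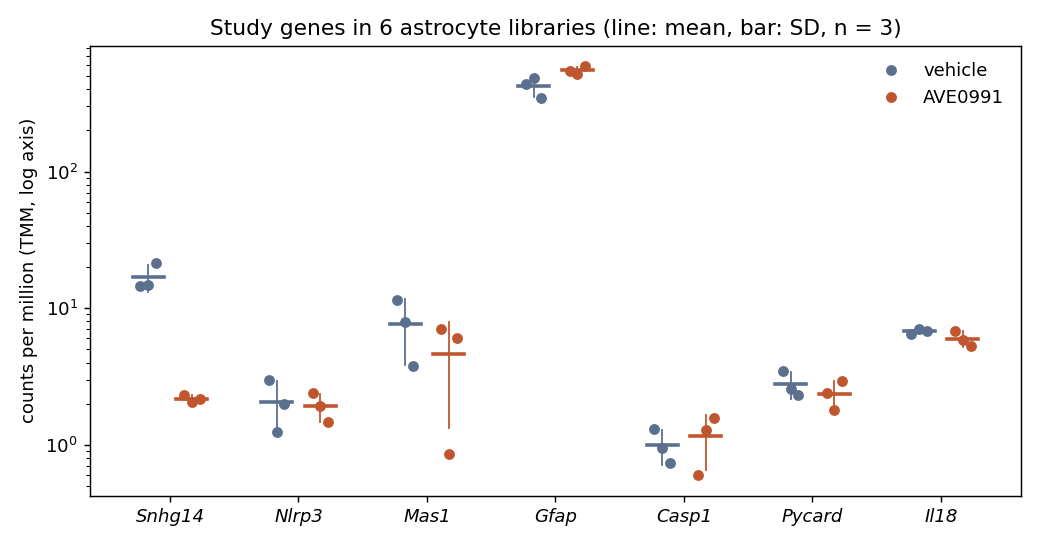
Normalised CPM (log axis) of the 7 measured study genes in each library, with vehicle in blue and AVE0991 in orange; the horizontal line is the mean and the bar the SD of 3 libraries. Snhg14 lies between 14.6 and 21.3 CPM in vehicle and between 2.05 and 2.31 CPM in AVE0991 libraries, while the groups overlap for the other genes except Gfap.

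Across all genes AVE0991 libraries had 7 genes higher and 169 lower at an adjusted p under 0.05. The 6 called protein-coding genes that were higher were Hif3a, Eomes, Nos2, Gpsm1, Dbp and Ablim3. Hif3a, a hypoxia-inducible factor subunit, rose 3.98-fold from 4.23 ± 0.301 to 16.8 ± 1.54 CPM (log2 fold change 1.99, SE 0.13, adjusted p = 0.0141). Eomes, a T-box transcription factor, rose 6.99-fold to 8.1 ± 0.137 CPM (2.81, SE 0.25, adjusted p = 0.0374). Nos2, the inducible nitric oxide synthase, rose 3.08-fold to a low level of 2.06 ± 0.269 CPM. Dbp, a transcription factor of the circadian output pathway, rose 1.69-fold from 69.4 ± 2.51 to 117.5 ± 2.66 CPM. Gpsm1, a G-protein signalling modulator, rose 1.70-fold and Ablim3, an actin-binding protein, 1.61-fold. Lgr6, Slc13a3, Nr1d1 and Shisa8 came next by p but did not pass, with adjusted p of 0.0509 to 0.051 and log2 differences of 1.34, 0.74, 0.52 and 2.62. Shisa8 was uneven, at 9.69, 27.95 and 31.89 CPM in AVE0991 replicates 1, 2 and 3, against 3.76 ± 0.459 CPM in vehicle libraries.

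The lower genes had a median log2 fold change of -0.93, and 72 of the 169 fell at least 2-fold. Among protein-coding genes with established names, the largest decreases were in Zfp945 (-1.66, SE 0.24), Samd5 (-1.64, SE 0.18), Zfp729b (-1.56, SE 0.17), Zfp994 (-1.52, SE 0.22) and Cdh12 (-1.44, SE 0.19), all on the log2 scale. Cdh12, a neuronal cadherin, fell from 50.7 ± 11.3 to 18.7 ± 2.49 CPM, and Samd5 from 57.4 ± 9.64 to 18.4 ± 3.12 CPM. Zfp930, Zfp738, Zfp758 and Zfp938 followed, with log2 fold changes between -1.44 and -1.38. After the GC correction none of these passed; among them Samd5 stood at -1.32, Zfp945 at -0.96, Zfp994 at -0.95, Cdh12 at -0.92 and Zfp758 at -0.68. Zfp genes encode zinc finger proteins, many of them repressors of closely related sequence, so counts of single members are uncertain where reads match several. Of 379 Zfp genes tested, 26 were called lower and 0 higher (Fisher's exact test of the lower calls, two-sided, p = 1.07e-16, a grouping made after the values were seen). Among genes with a GC content of at most 45%, 13.2% of 197 Zfp genes and 2.98% of 4022 other genes were called lower (odds ratio 4.94, 95% interval 3.02 to 7.84, Fisher's exact p = 1.64e-09). The named Zfp genes lay at 35.4% to 39% GC, so this split matched GC content only roughly. Both Fisher tests count genes as independent, although all genes come from the same libraries, so their p-values do not measure the spread between libraries. The median log2 fold change of all Zfp genes was -0.22, and -0.08 after the GC correction.

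These calls were close to the threshold: 174 of the 176 had an adjusted p of 0.03 or more, and all 176 showed no overlap between groups, as did 30.6% of all 20363 genes tested, where chance gives 10%. The counts moved with the tool and with single libraries: DESeq2 called 1012 genes higher and 1335 lower, limma-voom with quality weights 525 and 770, and leaving out any library other than AVE0991 replicate 1 left 0 calls by edgeR, with 3205 to 3818 genes at an unadjusted p under 0.05. Without AVE0991 replicate 1 the counts were 1386 and 995. Fitting circular RNA rows apart from gene rows was a choice made after the data were examined. One fit of both gave 1 gene higher and 1 lower, with 2 of the 176 calls kept and 4604 genes at an unadjusted p under 0.05.

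Transcripts of low GC content were lower in every AVE0991 library. Genes with a GC content of up to 40% had a median log2 fold change of -0.56, and 92 of 994 were called lower. Genes of 50 to 55% GC had a median of 0.13, and 0 of 4332 were called lower. The lower genes had a median GC content of 39%, the genes without a call 49.8%. The deviation of each library from the mean of the 6 correlated with GC content across genes, with a Spearman rho of -0.408 to -0.325 in the 3 vehicle libraries and 0.273 to 0.354 in the 3 AVE0991 libraries; genes are not independent replicates. The labels give no preparation batch, so whether the groups were prepared apart was not tested. With a per-library correction for GC, a fit added after the data were examined, edgeR called 1 gene higher, Hif3a (log2 fold change 1.86, adjusted p = 0.0304), and 0 lower, with 3108 genes at an unadjusted p under 0.05; DESeq2 with the same correction called 375 and 410. The median of the 169 lower genes went from -0.93 to -0.45 while their median SE stayed at 0.12, and 167 of them kept a negative sign. Part of the loss came from the adjustment: Gm30157, which had no GC value and was not corrected, stood at -2.52 in both fits and had an adjusted p of 0.0374 before and 0.155 after. Snhg14 had a GC content of 31% in its longest GENCODE transcript, of 6861 bases, which need not be the transcript that was counted.

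**Figure D2:**
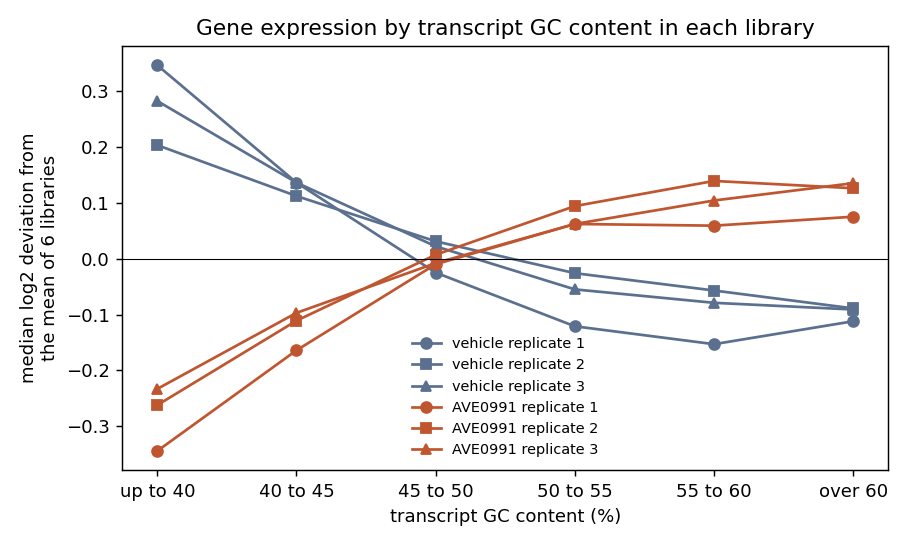
Median log2 deviation of genes from the mean of the 6 libraries (vertical axis) by transcript GC content in percent (horizontal axis), 1 line per library, vehicle in blue and AVE0991 in orange. At up to 40% GC the vehicle libraries lie between 0.20 and 0.35 and the AVE0991 libraries between -0.34 and -0.23, and the order is the opposite above 50%.

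The series is described as non-coding RNA profiling. Of 2354 long non-coding genes tested, 1 was called higher and 13 lower, and of 15500 protein-coding genes 6 and 141. The shares called, 0.595% and 0.948%, were not shown to differ when adjusted over all genes (odds ratio 0.625, 95% interval 0.333 to 1.08, two-sided Fisher's exact p = 0.101), and the non-coding genes were less abundant, with a median of 0.713 against 19.3 CPM. Adjusted within each biotype instead, 1 non-coding and 225 protein-coding genes were called, and the shares differed (odds ratio 0.0289, 95% interval 0.000731 to 0.163, two-sided Fisher's exact p = 6.02e-13). Separate adjustment gives each biotype its own p cutoff, so this odds ratio does not measure how often either class changed. LOC108167751 rose 1.54-fold from 21.9 ± 1.05 to 33.8 ± 1.4 CPM. Gm38592, Gm15510, B930059L03Rik and Gm26689 came next with log2 differences of 0.94 to 1.08 and did not pass. Besides Snhg14, the largest non-coding decreases were in Gm30157 (-2.52, SE 0.30), Gm46433 (-1.98, SE 0.31), AI504432 (-1.95, SE 0.27; -1.13 after the GC correction) and Gm38504 (-1.75, SE 0.23). Among 38 measured members of the list of well-known long non-coding RNAs, Snhg14 and Tug1 fell, Tug1 by 0.64 on the log2 scale (99.6 ± 1.56 to 63.9 ± 1.47 CPM, adjusted p = 0.0414; -0.08 after the GC correction), and 4 were lower when adjusted over the list alone. Kcnq1ot1 (-1.14), Meg3 (-0.78) and Neat1 (-0.62) did not pass over all genes. The list median was -0.24 and its camera adjusted p 0.0578. It was called lower with a mean of at least 1 CPM (-0.37, adjusted p = 0.0358), with DESeq2 (-0.22, adjusted p = 0.00317), and without vehicle replicate 3 (-0.24, adjusted p = 0.0331) or AVE0991 replicate 3 (-0.41, adjusted p = 0.0283). Its median was -0.16 without AVE0991 replicate 2 and -0.01 after the GC correction. In the Snhg14-Ube3a imprinted locus 2 of 8 members were called, Snhg14 and Ube3a, while Snrpn, a spliceosome gene of the same locus, stood at -0.09 (SE 0.11); the list had a median of -0.26 and a camera adjusted p of 0.114. It was called lower with DESeq2 (-0.25, adjusted p = 0.00114), while its median ranged from -0.40 to -0.07 without single libraries, the ends without vehicle replicate 2 and AVE0991 replicate 3, and was -0.03 after the GC correction.

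Gene lists fixed in advance asked which programmes and cell types moved. By camera 7 of 26 lists were higher in AVE0991 libraries and 0 were lower. None of the 7 held with an estimated correlation (adjusted p = 0.38 to 0.693 with an estimated correlation) and none passed fry (adjusted p of 0.0652 or more).

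The astrocyte identity list was higher, with 20 of 22 members above 0, a median log2 fold change of 0.54 and a camera adjusted p of 1.92e-05. Aldh1l1, a folate enzyme used as an astrocyte marker, stood at 114 ± 9.5 and 177 ± 28 CPM, and Aldoc, a glycolytic enzyme, at a log2 fold change of 0.80 (SE 0.18). No member passed over all genes (smallest adjusted p 0.0875), and 8 were higher when adjusted over the list alone. The list median was 0.29, 0.75 and 0.51 above the vehicle mean in AVE0991 replicates 1, 2 and 3, larger in replicates 2 and 3, which stand apart in cerebellar genes. The pan-reactive astrocyte list (13 members, median 0.38, camera adjusted p = 0.0382) was led by Vim, a filament gene at 1.60 (SE 0.48), and Cd44, a surface receptor at 0.88 (SE 0.30), neither of which passed. Its median was 0.19, 0.31 and 0.50 in AVE0991 replicates 1, 2 and 3, against -0.15 to 0.23 in vehicle libraries. After the GC correction its median log2 fold change was 0.24 (camera adjusted p = 0.0415). Vim was at 47.4, 144 and 198 CPM in AVE0991 replicates 1, 2 and 3, against 42.8 ± 8.46 CPM in vehicle libraries. The pan-reactive call was lost with a mean of at least 1 CPM (median 0.27) and without vehicle replicate 3 (0.26) or any 1 AVE0991 replicate (0.33 to 0.40), with an adjusted p of 0.0563 to 0.127. It was also lost with members of one list only (0.20, adjusted p = 0.1475), with DESeq2 (0.39, adjusted p = 0.0573) and after the length correction (0.33, adjusted p = 0.0635). The A1-type list (median 0.25, camera adjusted p = 0.212), the A2-type list (0.09, 0.169) and the synapse-facing astrocyte functions (0.32, 0.114; called higher after the GC correction, 0.26, adjusted p = 0.0415) were not called. In the A1-type list Iigp1 (-1.29) was lower when adjusted over the list alone, and in the A2-type list 3 members, among them Sphk1 (0.70) and Cd14 (0.75), were higher on that basis.

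Among inflammatory lists, the NLRP3 inflammasome and pyroptosis list was not called (17 members, median -0.18, camera adjusted p = 0.138). Its median ranged from -0.25 to -0.02 over 22 alternative settings. Nek7, a kinase that binds NLRP3, was the member that passed over all genes and fell 1.59-fold from 58.2 ± 3.99 to 36.5 ± 1.53 CPM (log2 fold change -0.67, SE 0.09, adjusted p = 0.043; -0.27 after the GC correction). Il1rap, the accessory chain of the interleukin-1 receptor, stood at -0.57 (SE 0.10, adjusted p = 0.0509), and 2 members were lower when adjusted over the list alone. The cytokine, chemokine and NF-kB list was higher (23 members, median 0.36, camera adjusted p = 0.00718). Of its members Nos2 passed, 3 were higher when adjusted over the list alone, and Nfkbiz, an inhibitor-family protein of NF-kB, stood at 0.88 (SE 0.20). The cytokine list median was 0.12, 0.30 and 0.44 in AVE0991 replicates 1, 2 and 3, and with a mean of at least 1 CPM it was 0.19 and not called (adjusted p = 0.0667). The interferon response list was higher (20 members, median 0.43, camera adjusted p = 0.0153), but its median was -0.02 in AVE0991 replicate 1 and 0.62 and 0.64 in replicates 2 and 3, the libraries that stand apart in cerebellar genes. Its call was lost without AVE0991 replicate 2 (0.36, adjusted p = 0.0681) or 3 (0.29, adjusted p = 0.056). Stat2 (0.79) and Oasl2 (1.05) were among its leading members and did not pass. Complement genes (18 members, median 0.13, camera adjusted p = 0.301) were not called, and 2 of them were lower when adjusted over the list alone.

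Of the remaining lists, disease-associated microglia (20 members, median 0.23, camera adjusted p = 0.0324), amyloid processing and clearance (24 members, median 0.20, 0.0333) and antioxidant and Nrf2 genes (20 members, median 0.20, 0.0333) were higher, with 0 members called over all genes. In AVE0991 replicates 1, 2 and 3 the amyloid median was 0.02, 0.23 and 0.22, against -0.07 to 0.04 in vehicle libraries. The antioxidant median was 0.14, 0.37 and 0.06 (vehicle -0.12 to 0.06), and the microglial one 0.22, 0.11 and 0.24 (vehicle -0.04 to 0.03). The amyloid call was lost without vehicle replicate 1 or AVE0991 replicate 2 or 3 (medians 0.20, 0.13 and 0.19), the antioxidant call without vehicle replicate 1 or AVE0991 replicate 1 or 2 (0.14, 0.24 and 0.13), by limma-voom (0.10) and after the length correction (0.15), and the microglial call without vehicle replicate 2 or AVE0991 replicate 1 or 3 (0.27, 0.19 and 0.20) and after the GC correction (0.10). With a mean of at least 1 CPM the amyloid and antioxidant lists were not called (adjusted p = 0.0667 each). Adjusted over the list alone, 1 microglial gene was higher, and 3 antioxidant genes were higher and 1 lower. B2m, the light chain of class I antigen presentation, stood at 0.50 (SE 0.10), Ece1, an enzyme that degrades amyloid-beta, at 0.61 (SE 0.21), and Gstm1, a glutathione transferase, at 0.62 (SE 0.11). Slc7a11, the cystine transporter, went the other way at -0.73 (SE 0.12, adjusted p = 0.0509). The medians of homeostatic microglia (-0.02), neuron (-0.03), mature oligodendrocyte (-0.08), oligodendrocyte precursor (-0.15), endothelial (-0.17), pericyte, smooth muscle and fibroblast (-0.06), ependymal and choroid plexus (-0.40) and blood and peripheral leukocyte (-0.46) lists were below 0 and not called. Neither were cell proliferation (-0.22), immediate early and dissociation stress (-0.12), cholesterol synthesis (0.02) or the renin-angiotensin system (-0.01). Without vehicle replicate 1 the mature oligodendrocyte (-0.34, adjusted p = 0.00762) and ependymal lists (-0.66, adjusted p = 0.000914) were called lower, as was the endothelial list without AVE0991 replicate 2 (-0.57, adjusted p = 0.0389). The camera adjusted p of all uncalled lists lay between 0.0578 and 0.979. For the renin-angiotensin and pericyte lists the camera direction was opposite to the median and mean, and for cholesterol synthesis the mean and the test were negative and the median positive.

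**Figure D3:**
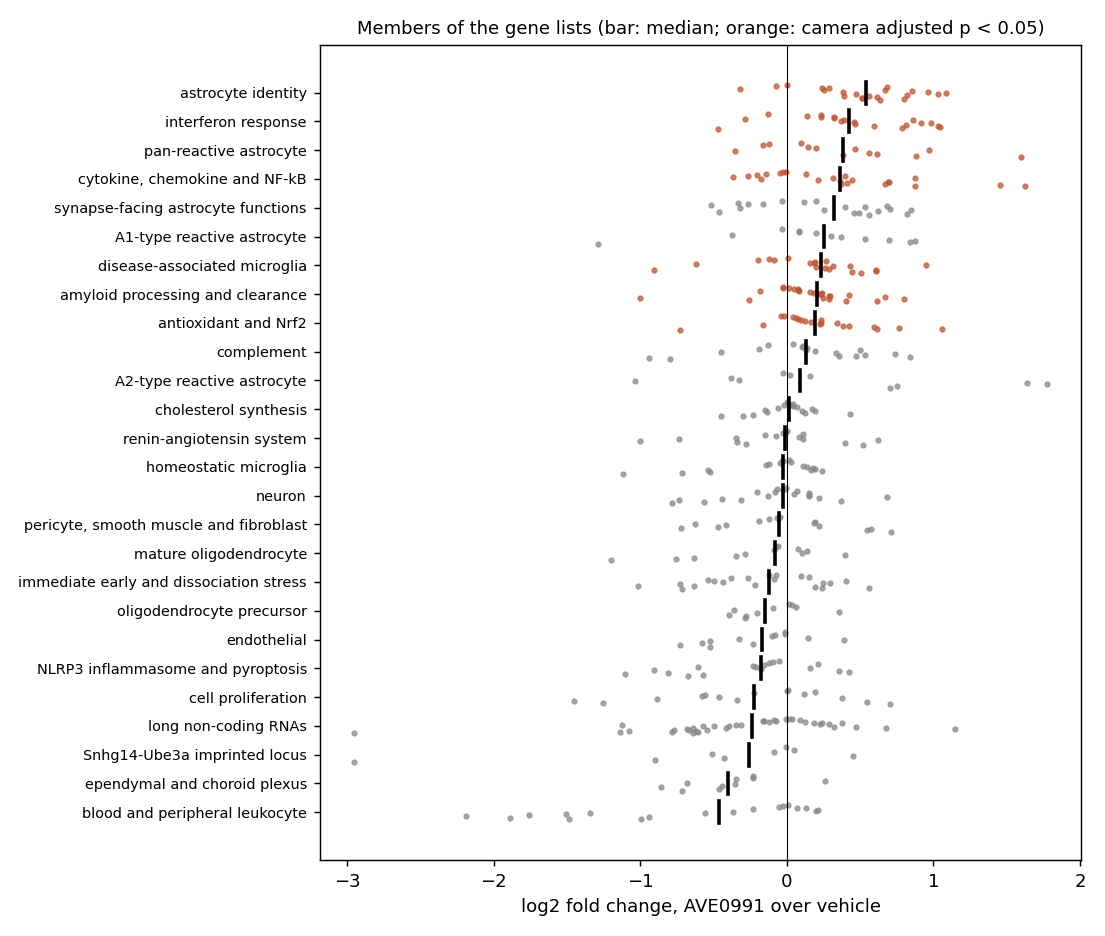
Log2 fold change of AVE0991 over vehicle (horizontal axis) for each measured member (point) of the 26 gene lists (rows), with the list median as a black bar; orange marks the 7 lists called by camera. The astrocyte identity list has the highest median, 0.54, and the blood and peripheral leukocyte list the lowest, -0.46.

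Genes of particular brain regions separated the AVE0991 libraries from one another. All 25 cerebellar genes of a list written after the data were examined had a positive log2 fold change. The list passed camera (adjusted p = 1.35e-08) but not with an estimated correlation (adjusted p = 0.576 with an estimated correlation). Its median was 3.35 and 3.23 above the vehicle mean in AVE0991 replicates 2 and 3, but 0.09 in replicate 1, where the vehicle libraries lay between -0.12 and 0.14. Cbln3, a granule cell gene, was at 10.3, 442 and 446 CPM in AVE0991 replicates 1, 2 and 3 and at 13.6 ± 9.81 CPM in vehicle libraries, and Pcp2, a Purkinje cell gene, at 2.17, 89.4 and 155 CPM against 2.7 ± 2.35 CPM. Eomes was the exception, at 8.18, 8.19 and 7.94 CPM. On the same scale hypothalamic genes lay at 1.16, -3.01 and -2.50 in AVE0991 replicates 1, 2 and 3, and striatal genes at 1.04, -1.35 and -1.86. Genes of medulla and pons lay at 0.10, 5.08 and 1.58, and genes of cortex and hippocampus at 0.10, -1.82 and -0.18. None of these 4 lists passed camera (adjusted p = 0.0546 to 0.309). After the GC correction all except the striatal list did (adjusted p = 0.0304 each; striatum 0.168), and none of the 4 passed with an estimated correlation before it (adjusted p = 0.705 to 0.824 with an estimated correlation). AVE0991 replicate 1 alone against the 3 vehicle libraries, with its spread assumed equal to theirs, gave 0 calls by edgeR, 2833 genes at an unadjusted p under 0.05, and 55 higher and 527 lower genes by DESeq2.

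**Figure D4:**
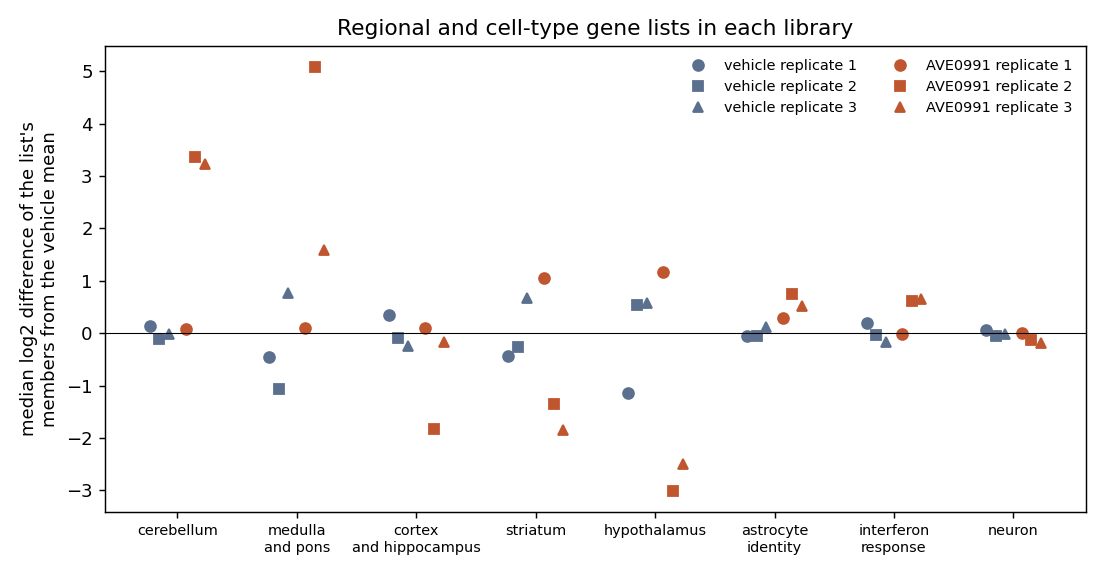
Median log2 difference from the vehicle mean (vertical axis) of regional and cell-type gene lists (horizontal axis) in each of the 6 libraries, vehicle in blue and AVE0991 in orange, with 1 symbol shape per replicate number. AVE0991 replicates 2 and 3 stand apart from the other 4 libraries in cerebellar genes, at 3.35 and 3.23, and AVE0991 replicate 1 lies at 0.09.

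Circular RNAs, which arise by back-splicing, were counted in the same table. Of 9626 tested, edgeR called 0, with 1048 at an unadjusted p under 0.05 and a smallest adjusted p of 0.341; DESeq2 called 98 higher and 80 lower. The smallest p values in each direction belonged to mmu_circ_0006703 (log2 difference -1.89, SE 0.27; 17 to 19 counts in AVE0991 and 59 to 84 in vehicle libraries) and mmu_circ_0015002 (1.75, SE 0.28). The next were mmu_circ_0007275 (-1.49, SE 0.22) and mmu_circ_0001916, with 0 counts in the vehicle and 111 in the AVE0991 libraries, at least 37.1-fold higher against a floor of 3 counts over the group; the floor covers counting error only. These 4 were taken by smallest p after the values were seen. The self-test recovered 12% of circular RNAs changed by a log2 of 1 and 67% of those changed by a log2 of 2.

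The authors' deposited table gives the same contrast. At a q under 0.05 and an absolute log2 fold change of at least 1, the authors' deposited table held 374 rows higher and 459 lower, of which 263 and 408 were gene rows and 111 and 51 circular RNA rows. Its log2 fold changes had a Spearman rho of 1 with those above across 20363 genes. At a q under 0.05 alone, the authors' deposited table called 1566 of these genes, and all 176 genes called here were among them with the same direction. Snhg14 had a log2 fold change of -2.93 and a q of 4.27e-32 in the authors' deposited table, and Nlrp3 one of -0.07 and a q of 0.961.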

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

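The comparison of counts with FPKM, the GC correction, and the tests on Snhg14 that involve Ube3a and the cerebellar libraries, were chosen after the results were seen. The deposited FPKM, a measure used in none of the comparisons above, gave a larger decrease of Snhg14 than the counts. FPKM was 14.1 ± 3.17 in vehicle and 0.653 ± 0.256 in AVE0991 libraries, 21.6-fold lower, against 7.73-fold lower in the counts. The transcript length implied by counts and FPKM together was 1229 ± 40 bases in vehicle and 3707 ± 1790 bases in AVE0991 libraries, a ratio of 3.02. Over 14044 genes with a mean of at least 100 counts, 95% of such ratios lay between 0.881 and 1.09, and 0 reached that of Snhg14. Of the other genes looked at, Ube3a had a ratio of 0.965 and Malat1 0.961, while Meg3, at 0.856, lay outside that range. So did Nlrp3, at 1.32, whose mean was below 100 counts and whose FPKM was 1.52-fold lower, against 1.07-fold lower in the counts.

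Of 3 technical explanations for the decrease of Snhg14, the first is reads of the antisense gene Ube3a. If a constant share of them was counted for Snhg14, they are argued against as the whole cause. The log2 fold change of Snhg14 was larger in size than that of Ube3a, by 2.053 (SE 0.222, taking both genes' errors as independent). A share that differed between the groups stays open, because the implied length of Snhg14 differed between them. Tissue of another brain region in AVE0991 replicates 2 and 3 stays open: in replicate 1 the log2 difference from the vehicle mean was 0.956 of that in replicates 2 and 3, but this is 1 library. GC content stays open too: the corrected log2 fold change was 0.663 of the uncorrected one, between the bounds set for either reading, and it went from -2.95 (SE 0.19) to -1.96 (SE 0.21, edgeR adjusted p = 0.155). The GC value used was that of a transcript of 6861 bases, longer than the implied lengths above. The correction may therefore not match the transcripts that were counted. The call ended with a smaller change and with fewer small p-values among all genes, 3108 against 4796 at an unadjusted p under 0.05; Gm30157, at -2.52 in both fits, lost its call too. An effect of AVE0991 and a GC trend that separates the groups cannot be told apart for the part that the correction removed.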

How the results depend on the processing

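Of the settings below, the GC and length corrections, the single fit with circular RNAs, the fit without the 3 most abundant unnamed rows, non-robust empirical Bayes, the fits of AVE0991 replicate 1 and the further circular RNA fits were chosen after the data were examined; the cause of the differences was not tested except where stated. All 176 called genes kept their call under DESeq2 and without a filter, and 175 under limma-voom. The astrocyte identity list lost its call with an estimated correlation and with fry, and under 0 other settings. Pseudocounts did not apply to counts, and non-robust empirical Bayes was not run for the lists, as camera does not use it. Circular RNAs had a median of 48.5 counts over the 6 libraries and a biological coefficient of variation of 38.2%, and what limited their calls was not tested.

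Genes higher and lower numbered 7 and 169 by edgeR, 58 and 379 without a filter, 18 and 328 with a mean of at least 1 CPM, 1012 and 1335 by DESeq2, 525 and 770 by limma-voom, 3 and 72 with an absolute log2 fold change of at least 1, and 164 and 769 at an adjusted p under 0.1. They were 1 and 1 in one fit with circular RNAs, 1 and 0 with the GC correction (3108 at an unadjusted p under 0.05; 375 and 410 by DESeq2), 13 and 170 with the length correction, and 7 and 70 without the 3 most abundant unnamed rows. AVE0991 replicate 1 gave 0 and 0 against the 3 vehicle libraries by edgeR (2833 at an unadjusted p under 0.05; 55 and 527 by DESeq2), and 406 and 1133 against vehicle replicates 2 and 3, with the lone library assumed to vary like the others. Leaving out single libraries gave 0 to 1386 higher and 0 to 995 lower, the highest without AVE0991 replicate 1 and 0 in every other case (3205 to 3818 at an unadjusted p under 0.05). Of the study genes, 0 to 1 were called without single libraries, and 0 with the GC correction and for AVE0991 replicate 1 against the 3 vehicle libraries. Circular RNAs were 98 higher and 80 lower by DESeq2, and 0 to 151 and 0 to 22 without single libraries. The odds ratio of non-coding calls was 0.0289 adjusted within each biotype. The authors' deposited table held 1821 rows at a q under 0.05 alone.

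The replicate block gave 0 higher and 0 lower genes by edgeR (3937 at an unadjusted p under 0.05, and 533 and 840 by DESeq2). It gave 0 study genes and 0 circular RNAs (941 at an unadjusted p under 0.05, and 121 and 89 by DESeq2). With it 7 lists were higher and 1 lower, the blood and peripheral leukocyte list (median -0.49, camera adjusted p = 0.00505). The numbers were not taken as pairing the libraries, since deviations from the group means correlated at -0.021, 0.092 and -0.353 within numbers 1, 2 and 3, and not every library correlated best with its own number.

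Lists higher and lower were 7 and 0 by camera, 3 and 1 with a mean of at least 1 CPM, 6 and 2 with DESeq2, 0 and 0 with an estimated correlation (0 at an unadjusted p under 0.05), 0 and 0 with fry (9 at an unadjusted p under 0.05), 4 and 1 for AVE0991 replicate 1 against the 3 vehicle libraries, 3 and 3 for it against vehicle replicates 2 and 3, and 3 to 6 and 0 to 2 without single libraries.

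Some values turned sign, many of them near 0 but not all. The interferon response and amyloid processing lists, called at medians of 0.43 and 0.20, turned in fits of AVE0991 replicate 1. So did Mas1, at -0.73 with all 6 libraries. Cholesterol synthesis had a median of -0.0095 with a mean of at least 1 CPM, -0.1102 by limma-voom, -0.0043 with the replicate block, -1e-04 in one fit with circular RNAs, -0.0385 with the GC and -0.0102 with the length correction. The renin-angiotensin list reached 0.0157 without a filter, 0.0706 with the GC correction and 0.0048 without the 3 rows; the pericyte list 0.0209 with the GC correction; cell proliferation 0.0381 with a mean of at least 1 CPM. AVE0991 replicate 1 against the 3 vehicle libraries gave Nlrp3 0.2213, Casp1 -0.7159, Il18 0.0282, interferon response -0.0168, homeostatic microglia 0.2643 and neuron 0.0021. Against vehicle replicates 2 and 3 it gave Nlrp3 0.5847, Casp1 -0.4677, Il18 0.0034, Mas1 0.2788, A2-type -0.0437, amyloid processing -0.0395, proliferation 0.1148, cholesterol synthesis -0.0154, homeostatic microglia 0.3577, immediate early genes 0.1586 and neuron 0.0351. Without single libraries the ranges were -0.354 to 0.2856 for Nlrp3, -0.0728 to 0.5263 for Casp1, -0.0132 to 0.21 for A2-type, -0.0771 to 0.1309 for cholesterol synthesis, -0.5676 to 0.1605 for endothelial, -0.1416 to 0.1414 for homeostatic microglia, -0.2913 to 0.0479 for immediate early, -0.4697 to 0.1046 for oligodendrocyte, -0.061 to 0.0451 for neuron, -0.1505 to 0.3006 for pericyte and -0.1267 to 0.0975 for renin-angiotensin genes.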

Other observations

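The lists of regional, clock and glucocorticoid genes and the tests on brain regions and on treatment in AVE0991 replicate 1 were chosen after the data were examined, as were the GC and length corrections and the fit without the 3 most abundant rows. Genes induced by glucocorticoids had positive values together in AVE0991 libraries. Of 18 measured targets 17 had a positive log2 fold change, with a median of 0.64 (camera adjusted p = 3.04e-07; 0.161 with an estimated correlation; fry adjusted p = 0.0112), and 7 were higher when adjusted over the list alone. Tsc22d3, a leucine zipper protein induced by glucocorticoids, stood at 0.99 (SE 0.26) and Plin4, a lipid droplet protein, at 1.51 (SE 0.33), neither of which passed over all genes. Over the 15 targets not looked at beforehand the camera p was 2.21e-05, and 0.055 with an estimated correlation, with 14 positive and a median of 0.39. Lcn2, Nfkbia, Fkbp5, Mt1 and Mt2 are among the 15 and belong to lists tested above, so this p is not independent of those lists. The median of all 18 was 0.43, 0.84 and 0.63 above the vehicle mean in AVE0991 replicates 1, 2 and 3, larger in the 2 libraries that stand apart in cerebellar genes. After the GC correction it was 0.33, 0.60 and 0.53. Glucocorticoid exposure is a hypothesis that these values leave open, as the astrocyte identity list was shifted by a similar size, with a median of 0.54, and 5 of the 18 targets are also in another list.

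Among clock genes of the day-to-dusk phase, 9 of 11 had a positive log2 fold change, with a median of 0.38 (camera adjusted p = 8.57e-05; 0.161 with an estimated correlation; fry adjusted p = 0.00818). Dbp rose, and 6 were higher when adjusted over the list alone. Of the 7 not looked at beforehand 5 were positive, with a median of 0.30. Their camera p was 0.0362, and 0.162 with an estimated correlation. The median of the 11 was 0.22 in AVE0991 replicate 1 and 0.51 and 0.56 in replicates 2 and 3, the libraries with cerebellar genes. After the GC correction it was 0.23, 0.27 and 0.33, against -0.05 to 0.01 in vehicle libraries. The median log2 fold change of the 7 not looked at beforehand was then 0.16. The 5 genes of the night-to-dawn phase, for which a shift in circadian phase predicts a decrease, had a median of -0.0967 over members that went both ways, from -0.72 for Clock to 0.56 for Cry1, which decides nothing.

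More genes were called lower than higher in AVE0991 libraries, 169 against 7. Length is argued against: with a length correction the lower genes' median was 0.989 of its value (95% bootstrap interval 0.942 to 1.02). The calls were then 13 higher and 170 lower. The 3 most abundant rows stay open as part of the excess. Without them the same genes' median was 0.979 of its value, which does not measure the excess, and the calls were 7 higher and 70 lower. Genes at an unadjusted p under 0.05 went from 2216 higher and 2580 lower to 2553 and 2414 without those rows. Tissue of another region in AVE0991 replicates 2 and 3 stays open as a cause of this excess. Without replicate 1 the calls were 1386 higher and 995 lower, 41.8% lower (exact 95% interval 39.8 to 43.8, counting genes as independent), so that more genes were called both ways. At an unadjusted p under 0.05 that fit had 3333 higher and 3158 lower, against 2216 and 2580 with all 6 libraries. The fit without replicate 2 had 1445 higher and 2373 lower at that p, and the fit without replicate 3 had 1168 and 2221. At that p the excess of lower genes was thus seen with replicate 1, which lacks the cerebellar signal, and not without it. As this rests on 1 library, it does not decide the question. In replicate 1 against the vehicle libraries the 169 lower genes had a median of -0.91, but they were chosen with that library included. GC content may account for about that part of the decrease which its correction removed, as the median was 0.485 of its value afterwards (0.422 to 0.565), and a treatment effect on transcripts of low GC content and a difference in library preparation between the groups both stay open, because the trend follows the groups and the labels give no batch. Of the 10 splits of the 6 libraries, 1 gave as many genes, the real one with 176 against at most 0 elsewhere, but 10 splits are too few for a share under 0.05.

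A count of 0 circular RNAs is met by any split, and 10 of the 10 splits gave as many by edgeR, 0 in each (1048 at an unadjusted p under 0.05 in the real one; 98 and 80 by DESeq2). For gene lists 4 of the 10 splits gave as many as the 7 of the real one, and the highest, with vehicle replicate 1 and AVE0991 replicates 1 and 3 on one side, gave 9. The number of called lists therefore did not set the real split apart from the others. The splits are in any case too few for a share under 0.05.

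Cerebellar genes were higher in AVE0991 replicates 2 and 3. GC content is argued against by a corrected median that was 0.932 of the uncorrected one (95% bootstrap interval 0.909 to 1.07), while treatment stays open, as the median of 0.086 in AVE0991 replicate 1, within the vehicle range of -0.119 to 0.142, is 1 library and part of the pattern itself. Different brain regions in the libraries are a candidate explanation: of the 25 cerebellar genes 0 are in another list and 23 reached 1 CPM in vehicle libraries. It also predicts lower genes of other regions in both, and the higher of the 2 cortical and hippocampal medians was -0.177, within the vehicle range of -0.238 to 0.343, but -0.339 after the GC correction, below the range of -0.25 to 0.385. Hypothalamic genes at -3.01 and -2.50 and striatal genes at -1.35 and -1.86 lay below their vehicle ranges, from -1.14 and -0.44 upwards, which goes with this hypothesis, while the labels name brain and no region.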
